A study of Mus musculus with 12 samples.

How the data were processed

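RNA was sequenced from Min6 cells, a mouse beta cell line, in 12 libraries of 4 groups with 3 libraries each. The groups were kept for 48 h in DMSO (the solvent control), in 1 µM of AS1842856 (a FoxO1 inhibitor, FoxOi), in 5 µM of loperamide (an opioid receptor agonist used against diarrhoea), or in both compounds (FoxOi_Loperamide). Per the labels, RNA was prepared with DNase treatment, made into stranded mRNA libraries and read as single reads of 50 bases. The labels do not say whether the libraries of a group come from separate cultures.

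The authors deposited a table of raw counts per gene and a table of FPKM values, each with 1 column per library. The submitters' processing notes name STAR 2.7.5a, Picard 2.19.2 and DESeq2, and the builds GRCm38 and mm10. The tool and strand setting of the counting step are not given in the sources used here. The deposited counts are whole numbers with a different total in each library. The deposited FPKM values equal the counts divided by gene length and by a library factor that lies within 0.354% of DESeq2 size factors, as checked on 10321 genes. Of the 55487 genes in the files, 98.8% have the location that GENCODE M21 gives, and the gene coordinates printed here are those of the files.

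Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with the group (minimum count 10, minimum total count 15), which left 16808 genes. Libraries were scaled with TMM, and a quasi-likelihood model with robust dispersion was fitted to all 12 libraries with the group as its only term. The comparisons were each compound against DMSO, the combination against DMSO and against each compound, and the interaction, which is the log2 effect of loperamide with the inhibitor minus its effect without. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. Log2 fold changes were fitted with a prior count of 0.125. Their standard error (SE) is the absolute log2 fold change divided by the square root of the F statistic of the test. Levels are counts per 1000000 of the TMM-scaled library size (CPM), mean ± SD over 3 libraries, and so differ from shares of all counts. "Higher" and "lower" refer to the first group named.

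Depth ran from 10640485 to 19499216 counts per library. A group with no count of a gene was given a floor of 3 counts over the group when a fold was computed. Floors cover counting error only, since reads were not tagged by molecule. The other group was taken at its mean CPM, so a fold called "at least" does not cover the error of that group. Pairs of libraries of the same group differed by 5.34 to 33.5 times the counting variance (chi-square per degree of freedom). On simulated data with 200 genes changed, the test for FoxOi against DMSO recovered 24 of 67 genes changed 1.5-fold, 57 of 67 changed 2-fold and 65 of 66 changed 4-fold, with 10 false calls among 16449 genes. For the interaction it recovered 14 of 67, 49 of 67 and 59 of 66, with 7 false calls among 16443 genes. The data held more called genes than these simulations changed, which loosens the adjusted p threshold, so recovery in the data may differ. A simulated list raised 1.5-fold was called, and 0 other lists were. Genes were drawn independently in that simulation, so it does not show how often lists of correlated genes are called falsely.

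Before the data were examined, 36 gene lists were fixed for beta cell function, other hormones and cell types, stress responses, metabolism and cell division. Of their 603 genes, 517 were tested, and 34 lists had at least 3 tested genes. The lists of acinar markers and opioid receptors had fewer. Lists were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, adjusted over the 34 lists, and again with a correlation estimated per list and with fry. Another 5 lists (feedback genes of ERK signalling, transport from the ER to the Golgi, the Dlk1-Dio3 locus, matrix metalloproteinases, and nuclear RNAs without poly(A) tails) were chosen after the data were seen and were adjusted among themselves.

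Genes were named by a rule fixed before the data were examined. It takes Ins1, Ins2, Gcg, Pdx1, Mafa, Nkx6-1, Foxo1, Neurog3, Aldh1a3, Pcsk1, Slc2a2 and Ucn3 in every comparison. It adds the 5 called genes with the largest rise and the 5 with the largest fall, among genes with a mean of at least 1 CPM, groups that do not overlap (not asked for the interaction) and no predicted-gene symbol. It further adds up to 4 members with the smallest adjusted p from each list that camera called or that had at least 3 called members. Genes outside the rule are named as chosen after their values were seen. Of the genes the rule takes from lists, 2 are not reported here and are left out of the counts of named genes, while the list tests keep all members.

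The labels number the libraries of each group 1 to 3, and libraries with the same number carry the same code in all 4 groups. The labels do not say what a number or its code stands for, and the test was fixed without a replicate block. Whether numbers pair the libraries was checked by correlating the deviations of log2 CPM from the group means. Of 18 pairs of libraries with the same number, 17 correlated above 0.1, against 1 of 36 pairs with different numbers, and 12 of 12 libraries correlated best on average with those of their own number. The numbers were taken to pair 2 groups when the lowest of the 3 same-number correlations was above 0.1. This held for every pair of groups except Loperamide and FoxOi_Loperamide, whose lowest correlation was 0.0915. The remaining same-number correlations of that pair were 0.328 and 0.341, and both groups paired with DMSO and with FoxOi. The low value therefore does not show that these groups are unpaired. Counts of calls with the number as a block are given beside the unblocked ones where they differ by over 1.5 times.

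Alternatives were DESeq2 size factors in place of TMM, no filter on low counts, the replicate number as a block, the DESeq2 1.42.0 Wald test, a fit to the 2 compared groups alone, limma on log2 FPKM with a pseudocount of 1 or 0.1 at a mean FPKM of at least 0.5, the same without that filter, leaving out each library in turn, and for lists the estimated correlation. Leaving out a library leaves 2 in its group. Figures were drawn with matplotlib 3.10.9.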

Results

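Gene expression was measured by mRNA sequencing in 12 libraries of the mouse beta cell line Min6 after 48 h in DMSO, in the FoxO1 inhibitor AS1842856 (FoxOi), in loperamide, or in both compounds (FoxOi_Loperamide), with 3 libraries per group. By the series title, the inhibitor serves as a model of beta cell dedifferentiation, with glucagon repression and insulin maturation as the questions asked of FoxO1. Total counts per library ran from 10640485 (Loperamide replicate 1) to 19499216 (FoxOi replicate 3). Ins2 took 3.56% or more of all counts in each DMSO library and 1.99% or less in each FoxOi library.

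**Figure D1:**
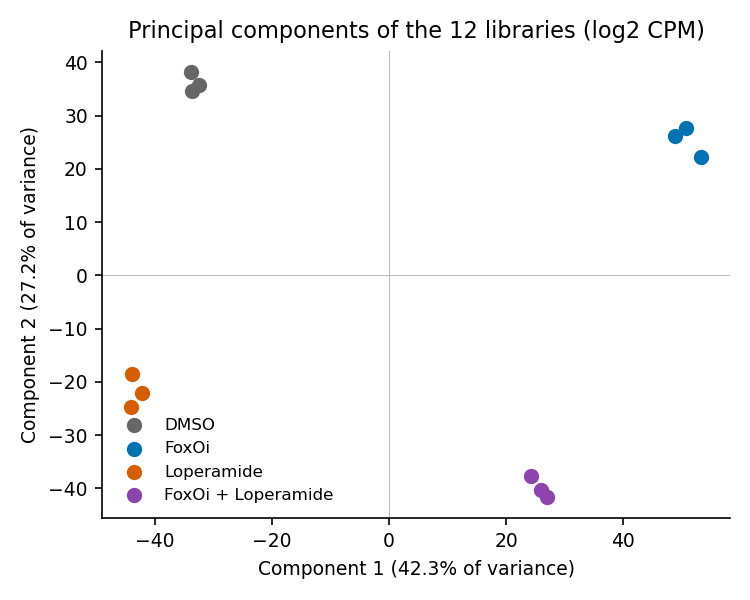
Principal components of log2 CPM of the 12 libraries, with 1 point per library coloured by group and the share of variance on each axis. Component 1 (42.3%) parts the libraries with the inhibitor from those without, component 2 (27.2%) parts those with loperamide from those without, and the 3 libraries of each group lie together.

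FoxOi was compared with DMSO to ask what the inhibitor does to the beta cell programme. Insulin and the transcription factors that maintain it fell. Mafa, an activator of the insulin genes (ENSMUSG00000047591, chromosome 15, 75745490 to 75748228), went from 811 ± 32.3 to 86.5 ± 22.4 CPM (SD, n = 3), a log2 fold change of -3.23 ± 0.15 (SE, adjusted p = 3.33e-09). Ins2 (ENSMUSG00000000215, chromosome 7, 142678656 to 142743381) fell by 1.36 ± 0.13 on the log2 scale, Ins1 (ENSMUSG00000035804, chromosome 19, 52264297 to 52265476) by 1.49 ± 0.14, and Pdx1, a master regulator of beta cells, by 1.14 ± 0.08. Nkx6-1, another beta cell factor, fell by 0.67 ± 0.11, Ucn3, a marker of mature beta cells, by 1.33 ± 0.21, and Foxo1 itself by 0.48 ± 0.11. Pcsk1, which encodes a proinsulin convertase, was at -0.11 ± 0.09 (adjusted p = 0.345).

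Gcg, which encodes glucagon (ENSMUSG00000000394, chromosome 2, 62474530 to 62483650), rose with FoxOi from 717 ± 131 to 1084 ± 196 CPM (SD, n = 3), a log2 fold change of 0.59 ± 0.19 (adjusted p = 0.027). This call was lost without DMSO replicate 1 (adjusted p = 0.0652), DMSO replicate 3 (0.124), FoxOi replicate 1 (0.0982) or FoxOi replicate 2 (0.103), and on unfiltered FPKM (0.0879). Within each replicate number Gcg was higher with FoxOi, at 1134 against 778 CPM in number 1, 1250 against 807 in number 2 and 868 against 567 in number 3. Slc2a2, the glucose transporter GLUT2, was low at 1.90 ± 0.37 CPM in DMSO and fell by 0.95 ± 0.33 (adjusted p = 0.0293), a call lost without DMSO replicate 1 (0.0671) or 2 (0.0889) and without FoxOi replicate 1 (0.0918) or 3 (0.107), and on unfiltered FPKM (0.125). Neurog3, a factor of endocrine progenitors, had 0 counts in every group. Aldh1a3, a marker of dedifferentiated beta cells, had 24 counts over the DMSO libraries, 36 over FoxOi, 10 over Loperamide and 14 over FoxOi_Loperamide, and was too low to be tested.

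The gene groups behind beta cell function fell together. Of 16 beta cell transcription factors, 12 fell and 0 rose, Nkx2-2 by 2.17 ± 0.10, Pax6 by 1.48 ± 0.07 and Isl1 by 1.37 ± 0.07 (list median -0.99, camera adjusted p = 2.77e-15, adjusted p = 0.00599 with an estimated correlation). Of 25 genes of glucose sensing and exocytosis, 16 fell and 2 rose, among them the fatty acid receptor Ffar1 at -2.47 ± 0.11 and the potassium channel subunit Kcnj11 at -1.13 ± 0.08 (adjusted p = 0.0102 with an estimated correlation). These were the 2 lists called by camera with an estimated correlation, against 19 of 34 at the preset correlation. Of 18 genes of insulin processing and granules, 12 fell and 1 rose, with the convertase Pcsk2 at -1.26 ± 0.09 and the granule proteins Chga at -1.27 ± 0.12 and Chgb at -1.24 ± 0.08 (camera adjusted p = 1.05e-06, adjusted p = 0.0792 with an estimated correlation). Counts of called members in each list were adjusted over all genes. Adjusted over the list alone, the beta cell factors gave 12 lower and 1 higher, immediate early genes 12 higher and 3 lower, hypoxia genes 6 higher and 1 lower and neuronal markers 7 lower. The other called lists kept their counts.

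Genes that beta cells normally keep low went the other way. Of 13 such disallowed genes, 8 rose and 2 fell, with Ldha, lactate dehydrogenase, at 4.13 ± 0.27 and the lactate transporter Slc16a1 at 2.01 ± 0.17 (adjusted p = 0.0792 with an estimated correlation). Of 17 glycolysis genes, 13 rose and 2 fell (0.0792), and of 11 hypoxia genes 6 rose, including Adm at 3.81 ± 0.26 (0.0792). Stress programmes rose as well: 21 of 25 targets of ATF4, the factor of the integrated stress response, with Atf3 at 3.73 ± 0.23 (adjusted p = 0.0792 with an estimated correlation), 13 of 17 p53 targets, while 1 fell, with the cell cycle inhibitor Cdkn1a at 2.43 ± 0.13 (0.0792), 6 of 13 NRF2 targets with Hmox1 at 2.39 ± 0.16 (0.106) and 21 of 25 lysosomal genes with Neu1 at 1.17 ± 0.09 (0.106). Of 18 immediate early genes 11 rose and 3 fell (0.0792), with Fosl1 at 4.49 ± 0.36. The values in brackets without a name are adjusted p with an estimated correlation.

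Mitosis and ER genes fell. Of 24 mitosis genes 21 fell, with Nusap1 at -1.44 ± 0.10 (list median -0.67, adjusted p = 0.139 with an estimated correlation). Of 22 ER chaperones and genes of the unfolded protein response 16 fell, with Derl3 at -3.33 ± 0.21 (adjusted p = 0.0966 with an estimated correlation). The largest rises by the naming rule were those of Pla2g2e, a secreted phospholipase (0 counts in DMSO, at least 182-fold higher), Mmp10, a matrix metalloproteinase (0 counts, at least 91.1-fold higher), Gpnmb and Prss56 (1 and 2 counts in DMSO, 1214 and 271 with FoxOi) and Areg, an EGF receptor ligand (8.39 ± 0.21). The largest falls were those of Fxyd7 (-4.16 ± 0.34), Baiap3 (-4.12 ± 0.27), Grrp1 (-4.10 ± 0.56), Nme9 (-3.58 ± 0.52) and Muc4 (-3.49 ± 0.62), whose call was lost on unfiltered FPKM (adjusted p = 0.0605).

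Other lists moved less uniformly with FoxOi. Cholesterol synthesis genes rose in 13 of 25 cases and fell in 1 (adjusted p = 0.395 with an estimated correlation) and ribosomal protein genes in 11 of 22 (0.663). Of 11 neuronal markers 6 fell (0.106), of 9 alpha cell markers 6 fell and 2 rose (0.254), of 4 ductal markers Spp1 rose by 4.94 ± 0.15 and Krt7 fell by 1.08 ± 0.16 (0.128), and of 3 macrophage and leukocyte markers Cd68 rose by 3.09 ± 0.17 (0.0792). FoxO targets, chosen as known targets of the family, were split, with 7 of 22 higher and 8 lower (camera adjusted p = 0.901), Klf6 at 2.03 ± 0.15 and Tnfsf10 at -2.01 ± 0.25. The call for alpha cell markers was lost with no filter (0.0503), without DMSO replicate 3 (0.105), without FoxOi replicate 1 (0.0701), without FoxOi replicate 2 (0.0703) and without FoxOi replicate 3 (0.0988). That for ductal markers was lost with no filter (0.12). That for ribosomal proteins was lost without DMSO replicate 3 (0.104) and without FoxOi replicate 1 (0.0855). That for neuronal markers was lost without FoxOi replicate 2 (0.0543). In all, 6881 of 16808 genes were called, 3476 higher and 3405 lower, 1860 of them changed at least 2-fold.

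**Figure D2:**
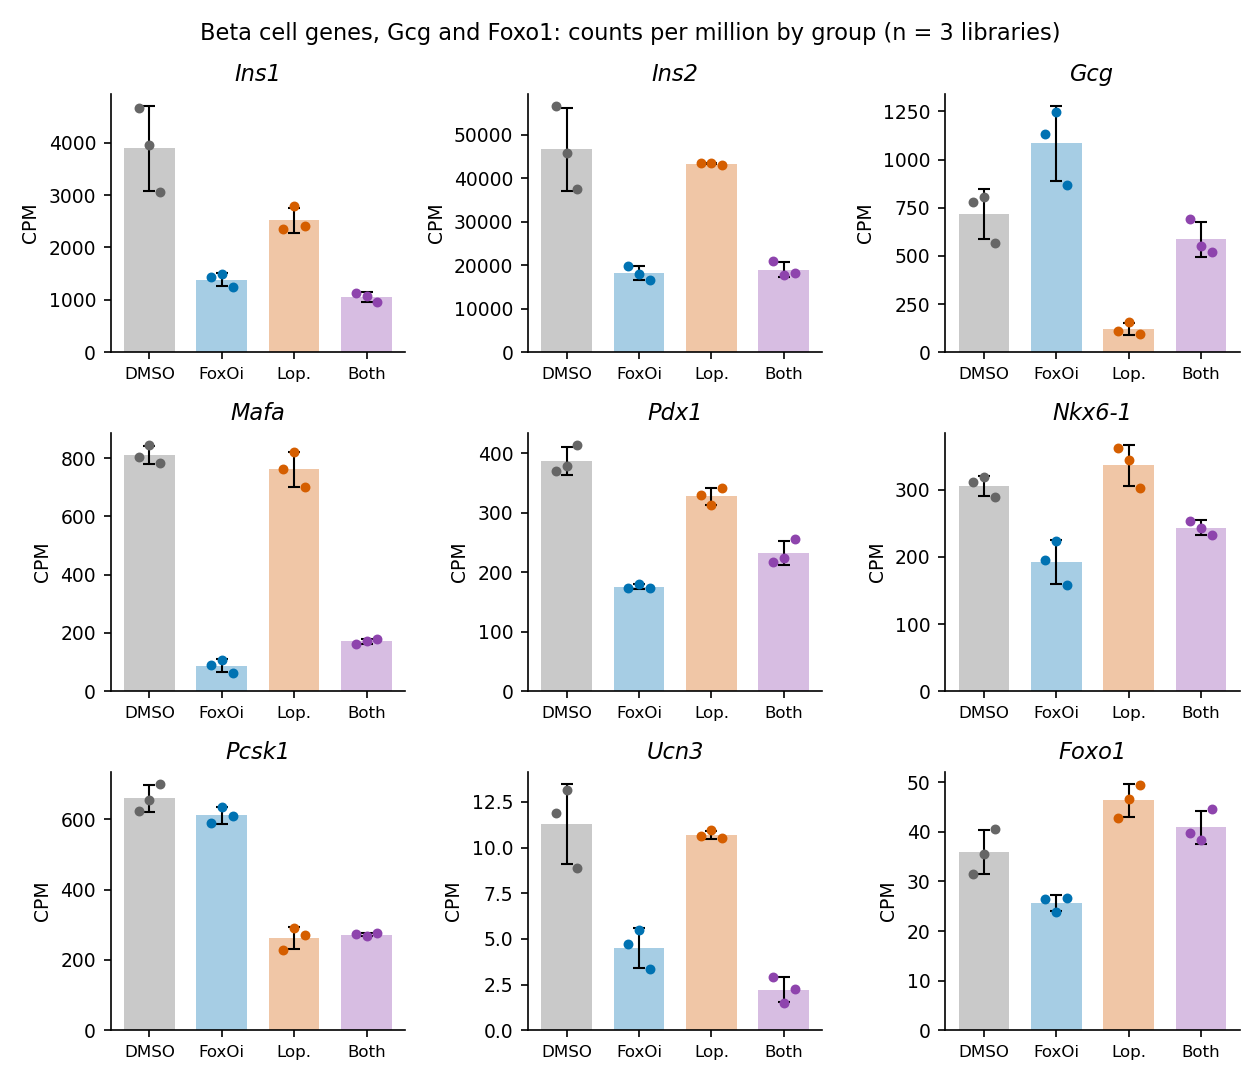
CPM of 9 genes in the 4 groups, with bars at the mean of 3 libraries, error bars of 1 SD and 1 point per library; Lop. is loperamide and Both is FoxOi_Loperamide. Mafa is at 811 CPM in DMSO and 86.5 with FoxOi, and Gcg is at 1084 CPM with FoxOi and 121 with loperamide.

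Loperamide was compared with DMSO to show its effect without the inhibitor. Most hormone genes outside insulin fell, glucagon among them, while Mafa was at -0.09 ± 0.14 (adjusted p = 0.66). Gcg went from 717 ± 131 to 121 ± 30.7 CPM (SD, n = 3), a log2 fold change of -2.56 ± 0.21 (adjusted p = 2.21e-06). Pcsk1 fell by 1.33 ± 0.09 and Ins1 by 0.63 ± 0.13, while Ins2 was at -0.10 ± 0.13 (adjusted p = 0.575), Ucn3 at -0.08 ± 0.20 (0.784), Nkx6-1 at 0.14 ± 0.11 (0.38) and Slc2a2 at -0.38 ± 0.33 (0.406). Pdx1 was called at -0.24 ± 0.08 (adjusted p = 0.0367), a call lost without DMSO replicate 2 (0.0586) or 3 (0.0795) and without Loperamide replicate 1 (0.0786), 2 (0.124) or 3 (0.0522). It was also lost with no filter (0.066), in the fit to the 2 groups alone (0.0649) and on unfiltered FPKM (0.0556). Foxo1 was called at 0.37 ± 0.11 (adjusted p = 0.0157), a call lost without DMSO replicate 1 (0.0892), DMSO replicate 2 (0.0611) or Loperamide replicate 3 (0.0691), and on unfiltered FPKM (0.0601).

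Of 9 other endocrine hormone genes 7 fell with loperamide, with cholecystokinin (Cck) at -1.57 ± 0.11, somatostatin (Sst) at -2.40 ± 0.49 and Tph1, of serotonin synthesis, at -2.25 ± 0.21 (adjusted p = 0.0499 with an estimated correlation). Alpha cell markers fell in 5 of 9 cases and rose in 1, with Ttr at -2.64 ± 0.25 (0.0499), and insulin processing and granule genes in 10 of 18, with Vgf at -1.72 ± 0.08 and Pam at -1.43 ± 0.13 (0.0499). ER chaperones and genes of the unfolded protein response gave the strongest camera result: 18 of 22 fell and 1 rose, with Sdf2l1 at -2.42 ± 0.11, Pdia4 at -1.78 ± 0.08 and Pdia6 at -1.74 ± 0.08 (list median -1.25, adjusted p = 0.00291 with an estimated correlation). All 24 mitosis genes fell (median -1.05, 0.0499), with Ube2c at -1.49 ± 0.12. These 5 lists were called with an estimated correlation, against 16 at the preset one.

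Cholesterol synthesis genes rose in 21 of 25 cases and fell in 1, with Msmo1 at 1.38 ± 0.11 (adjusted p = 0.118 with an estimated correlation). FoxO targets rose in 13 of 22 cases, Fbxo32 by 1.37 ± 0.14 and Mxi1 by 1.20 ± 0.09 (0.118). Oxidative phosphorylation genes fell in 18 of 27 cases, Ndufa1 by 0.80 ± 0.10 (0.409), and DNA replication genes in 11 of 23, Rrm2 by 1.56 ± 0.12 (0.51). Rises were called for p53 targets (9 of 17, 0.183), ATF4 targets (13 of 25, 0.394), interferon response genes (9 of 20, 0.435), fatty acid synthesis (7 of 15, 0.476), glucose sensing and exocytosis (11 of 25, 0.194) and the FoxO family (3 of 4, 0.183). Ductal markers were called lower (2 of 4, 0.248). Among these rises 3 genes of glucose sensing and exocytosis, 2 ATF4 targets and 1 gene each of the p53, interferon and fatty acid synthesis lists were called lower. The bracketed values are adjusted p with an estimated correlation. When adjusted over the list alone, 15 FoxO targets and 12 p53 targets were higher, 19 ER, 20 oxidative phosphorylation and 13 DNA replication genes were lower, and 2 cholesterol synthesis genes were lower. The call for ductal markers was lost with no filter (0.186) and without Loperamide replicate 3 (0.0655). That for the FoxO family was lost with the replicate block (0.0666), without DMSO replicate 1 (0.0605), without DMSO replicate 3 (0.0633) and without Loperamide replicate 2 (0.0742). That for fatty acid synthesis was lost without DMSO replicate 1 (0.0605), without DMSO replicate 2 (0.0618) and without Loperamide replicate 3 (0.0872). That for glucose sensing and exocytosis was lost without DMSO replicate 3 (0.0597). The opioid receptor genes Oprm1 and Oprd1 stood at 1.88 ± 0.37 and 1.11 ± 0.41 CPM in DMSO (SD, n = 3).

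The largest rises by the naming rule were those of the mitochondrial tRNA genes mt-Ti (5.11 ± 0.33), mt-Tm (4.26 ± 0.48) and mt-Tw (3.51 ± 0.33), of Sema6a (3.74 ± 0.19) and of Rspo1 (3.17 ± 0.60). The tRNA genes were low, at means of 0.193, 0.129 and 0.574 CPM in DMSO and 7.18, 2.71 and 6.63 with loperamide. The largest falls were those of Tcim (-4.10 ± 0.32) and Etv4, an ETS factor (-3.66 ± 0.23), and of Il4, Yipf7 and Tpsab1, which had 1, 1 and 2 counts with loperamide and 40, 24 and 36 in DMSO. The Tpsab1 call was lost without DMSO replicate 1 (adjusted p = 0.11) and without Loperamide replicate 1 (0.0653), 2 (0.0746) or 3 (0.106), and on FPKM with pseudocount 1, filtered (0.179) or not (0.312). In all, 5370 genes were called, 2713 higher and 2657 lower, and 1023 changed at least 2-fold. With the replicate number as a block the count was 8179.

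The combination was compared with DMSO to show both compounds together. The insulin genes and Pcsk1 fell, as did most granule genes. Ins1 fell by 1.89 ± 0.14, Ins2 by 1.29 ± 0.13, Mafa by 2.25 ± 0.15, Pdx1 by 0.74 ± 0.08, Ucn3 by 2.34 ± 0.23 and Pcsk1 by 1.28 ± 0.09. Gcg was at -0.29 ± 0.19 (adjusted p = 0.247), Foxo1 at 0.19 ± 0.11 (0.161) and Slc2a2 at -0.57 ± 0.32 (0.16). Gcg was called with no filter (0.0191) and with the replicate block (0.0293), and Foxo1 with that block (0.0309). Nkx6-1 was called at -0.33 ± 0.11 (adjusted p = 0.0235), a call lost without DMSO replicate 1 (0.0501) or 2 (0.0942), without FoxOi_Loperamide replicate 2 (0.0599) or 3 (0.0785), and on unfiltered FPKM (0.0799).

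Of 18 insulin processing and granule genes 16 fell with both compounds, with Ptprn at -1.70 ± 0.08 and Iapp, islet amyloid polypeptide, at -1.55 ± 0.10 (list median -1.28, adjusted p = 0.0077 with an estimated correlation). Of 22 ER chaperones and genes of the unfolded protein response 19 fell, with Sdf2l1 at -3.13 ± 0.11 and Hyou1 at -2.39 ± 0.09 (median -1.62, adjusted p = 0.00457 with an estimated correlation). Of 17 p53 targets 15 rose, with Phlda3 at 3.49 ± 0.20 and Cdkn1a at 2.56 ± 0.13 (camera adjusted p = 1.41e-14, adjusted p = 0.012 with an estimated correlation). Beta cell factors (10 of 16 lower) and glucose sensing genes (15 of 25 lower, 4 higher) were called too, each with adjusted p = 0.0199 with an estimated correlation. These 5 lists held with an estimated correlation, against 14 at the preset one and 17 with the replicate block. Cholesterol synthesis rose in 21 of 25 cases (adjusted p = 0.0812 with an estimated correlation), lysosomal genes in 18 of 25 (0.226), ATF4 targets in 18 of 25 (0.299), ribosomal protein genes in 18 of 22 (0.529) and interferon genes in 10 of 20 (0.5). Other hormones fell in 7 of 9 cases (0.0665), alpha cell markers in 6 of 9 (0.174), calcium handling genes in 10 of 19 (0.312) and mitosis genes in 18 of 24 (0.5). Called the other way were 3 interferon genes, 2 calcium handling genes, 1 lysosomal gene, 1 p53 target and 1 alpha cell marker. Counted when adjusted over the list alone, 11 beta cell factors, 20 ER and 11 calcium handling genes were lower, and 22 cholesterol synthesis and 21 ribosomal protein genes were higher. The call for calcium handling was lost without DMSO replicate 3 (0.0523).

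The largest falls with both compounds by the naming rule were those of Derl3, of ER-associated degradation (-5.87 ± 0.28), Adam11 (-4.95 ± 0.59), Wdr64 (-4.79 ± 0.48), C1qtnf1 (-4.74 ± 0.14) and Dbh, which had 3 counts with both compounds and 168 in DMSO. The largest rises were those of Gpnmb and Dtna, which had 1 and 2 counts in DMSO and 138 and 127 with both compounds, of Rspo1 (4.82 ± 0.48), of the adenosine receptor gene Adora2b (4.62 ± 0.30) and of Pla2g2e. Pla2g2e, with 0 counts in DMSO, had 9 with both compounds, and its call was lost on unfiltered FPKM (adjusted p = 0.0616). Its mean was 2.66-fold above the floor, which leaves out the error of the 9 counts. In all, 7642 genes were called, 3749 higher and 3893 lower, and 2317 changed at least 2-fold.

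**Figure D3:**
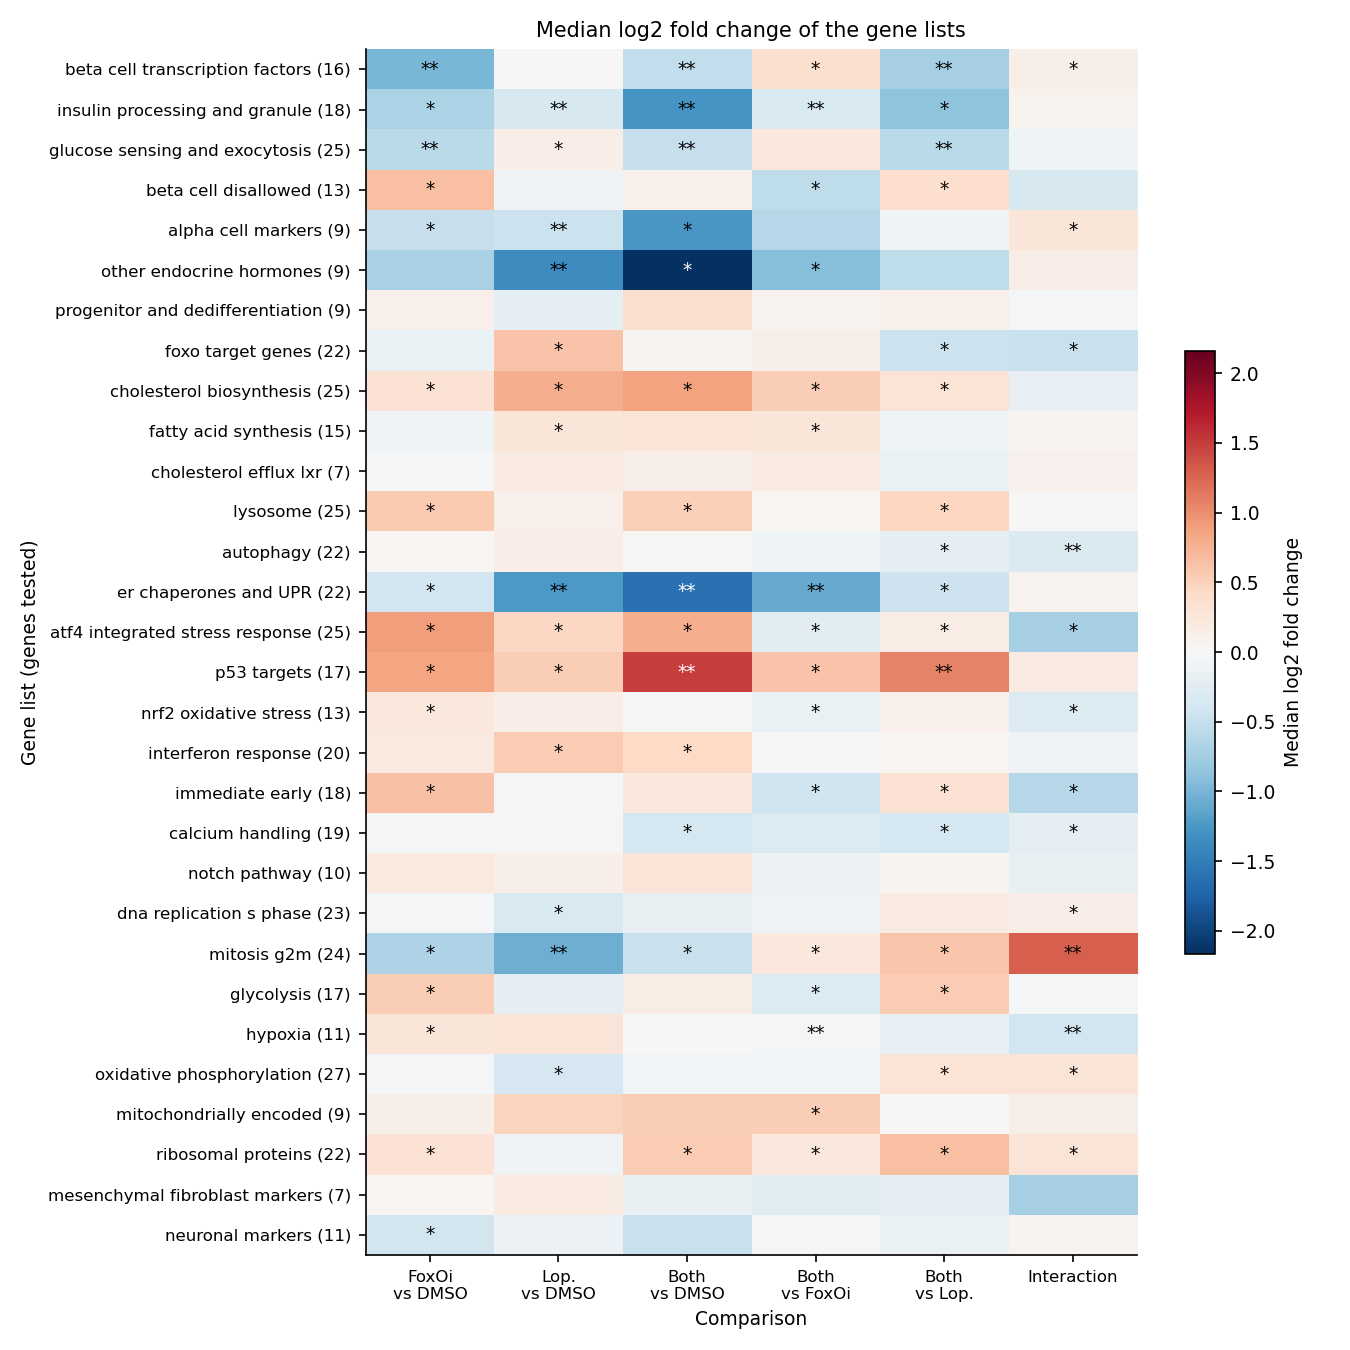
Median log2 fold change (colour) of the 30 fixed lists with at least 5 tested genes (rows, genes tested in brackets) in 6 comparisons (columns; Lop. is loperamide, Both is FoxOi_Loperamide). A star marks a list called by camera at the preset correlation and a pair of stars a list called with an estimated correlation too; ER chaperones have medians of -1.25 and -1.62 against DMSO in the Loperamide and FoxOi_Loperamide columns.

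The combination was compared with FoxOi to ask what loperamide adds once the inhibitor is present. Part of the beta cell programme rose: Mafa by 0.98 ± 0.14, Pdx1 by 0.40 ± 0.08, Foxo1 by 0.67 ± 0.11 and Pax6 by 0.87 ± 0.07. Ins2 was at 0.07 ± 0.13 (adjusted p = 0.742) and Slc2a2 at 0.38 ± 0.34 (0.449), and Gcg fell by 0.89 ± 0.20, Pcsk1 by 1.17 ± 0.09 and Ucn3 by 1.01 ± 0.24. Nkx6-1 was called at 0.33 ± 0.11 (adjusted p = 0.0375), but not in the fit to the 2 groups alone (0.0605), on unfiltered FPKM (0.0943), without FoxOi replicate 1 (0.056) or 3 (0.151), or without FoxOi_Loperamide replicate 1 (0.103), 2 (0.0841) or 3 (0.0523). Ins1 was called at -0.40 ± 0.13 (0.0389), but not without FoxOi replicate 1 (0.124) or 2 (0.136) or FoxOi_Loperamide replicate 2 (0.0824) or 3 (0.136). The Ins1 call was also lost on FPKM, at 0.0796 with pseudocount 1, 0.0781 with 0.1 and 0.141 unfiltered.

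Beta cell factors rose in 9 of 16 cases and fell in 3 (adjusted p = 0.111 with an estimated correlation). ER chaperones and genes of the unfolded protein response fell in 20 of 22 cases, Hspa5 by 1.70 ± 0.10 and Hyou1 by 1.49 ± 0.09 (adjusted p = 0.00825 with an estimated correlation), and insulin processing and granule genes in 10 of 18, Pam by 2.15 ± 0.13 (0.0472). Hypoxia genes fell in 5 of 11 cases (0.0472), and the markers Spp1 (-7.56 ± 0.18), Csf1r (-3.71 ± 0.69) and Cd68 (-1.97 ± 0.15) fell in the short ductal and macrophage lists (both 0.0472). These 5 lists held with an estimated correlation, against 18 at the preset one. The ductal and macrophage calls rest on few tested genes, and the ductal marker Krt7 was not called. Krt19, Cftr and Sox9 of the ductal list were too low to be tested. So were Ptprc, Adgre1 and Itgam of the macrophage list, and the list results do not cover these markers. Disallowed genes fell in 7 of 13 cases, Ldha by 3.36 ± 0.25 (0.0613), other hormones in 5 of 9 (0.0613), glycolysis in 10 of 17 (0.218), immediate early genes in 9 of 18 (0.107), ATF4 targets in 7 of 25 (0.566) and NRF2 targets in 4 of 13 (0.282). Rises were called for p53 targets (10 of 17, 0.0613), cholesterol synthesis (15 of 25, 0.121), fatty acid synthesis (8 of 15, 0.282), mitosis (5 of 24, 0.6), mitochondrially encoded genes (5 of 9, 0.566) and ribosomal proteins (4 of 22, 0.615). Called the other way were 3 immediate early genes, 3 glycolysis genes and 1 gene each of the disallowed, cholesterol synthesis and fatty acid synthesis lists. Of the 5 mitochondrially encoded genes that rose, mt-Nd3, mt-Nd4l and mt-Nd4 have 98.0%, 98.8% and 62.2% of their 50-base stretches in annotated transcripts of other genes. The call for mt-Nd4l was lost without FoxOi replicate 2 (adjusted p = 0.107) or 3 (0.0703), without FoxOi_Loperamide replicate 1 (0.105) and on unfiltered FPKM (0.083), and that for mt-Nd1 without the same libraries (0.0621, 0.0716 and 0.0769) and on unfiltered FPKM (0.0643). For mt-Nd4 (adjusted p = 0.0455), named after its value was seen, values of the alternatives were not tabulated. The untested members mt-Co2, mt-Co3, mt-Atp6 and mt-Atp8 had 5, 6, 0 and 1 counts over all libraries, so this list covers part of the mitochondrial genes and shared reads were not excluded for it. Within lists, adjusted over the list alone, 18 cholesterol synthesis, 9 fatty acid synthesis and 11 p53 genes and 2 ribosomal protein genes were higher, 9 ATF4 targets were lower, and 1 other hormone was higher. The call for NRF2 targets was lost without FoxOi replicate 1 (0.0775), without FoxOi replicate 3 (0.0667), without FoxOi_Loperamide replicate 1 (0.0581) and without FoxOi_Loperamide replicate 2 (0.0524). That for mitochondrially encoded genes was lost without FoxOi replicate 3 (0.0741) and without FoxOi_Loperamide replicate 1 (0.096). That for ribosomal proteins was lost without FoxOi_Loperamide replicate 1 (0.0636). That for mitosis was lost without FoxOi_Loperamide replicate 2 (0.0941).

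Pla2g5, a phospholipase, had 241 counts with FoxOi and 0 with both compounds (at least 73.8-fold lower), Il4 had 828 and 3, and Tpsab1 932 and 3. Tll1 fell by 6.43 ± 0.75 and Spp1 was among the 5 largest falls. Adora2b (3.35 ± 0.25), mt-Ti (3.96 ± 0.33), mt-Tm (2.65 ± 0.45), mt-Tw (2.48 ± 0.31) and the Notch ligand gene Dll1 (2.48 ± 0.19) rose most. The tRNA genes were low here too, at means of 0.214, 0.201 and 0.756 CPM with FoxOi. With both compounds they were at 3.50, 1.30 and 4.29 CPM. In all, 4465 genes were called, 1926 higher and 2539 lower, and 1107 changed at least 2-fold. With the replicate number as a block the count was 7504, and without FoxOi replicate 2 the calls were 1270 higher and 2014 lower.

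The combination was compared with Loperamide to show the inhibitor's effect once loperamide is present. Mafa fell by 2.15 ± 0.15, Ins1 by 1.26 ± 0.13, Ins2 by 1.19 ± 0.13, Ucn3 by 2.26 ± 0.23, Pdx1 by 0.50 ± 0.08 and Nkx6-1 by 0.47 ± 0.11. Gcg rose by 2.27 ± 0.20, from 121 ± 30.7 to 586 ± 91.2 CPM (SD, n = 3, adjusted p = 3.58e-06). Foxo1 was at -0.18 ± 0.11 (adjusted p = 0.196), Pcsk1 at 0.05 ± 0.09 (0.695) and Slc2a2 at -0.19 ± 0.34 (0.698). Foxo1 was called with the replicate block (0.0445).

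Of 16 beta cell factors 14 fell, with Nkx2-2 at -2.13 ± 0.10 (adjusted p = 0.00958 with an estimated correlation), and of 25 genes of glucose sensing and exocytosis 17 fell, with Ffar1 at -2.37 ± 0.11 (0.00333). Of 17 p53 targets 12 rose and 1 fell, with Phlda3 at 2.54 ± 0.19 (0.0458). These 3 lists held with an estimated correlation, against 17 at the preset one. Rises were also called for mitosis (19 of 24, 0.346), ribosomal proteins (21 of 22, 0.346), oxidative phosphorylation (18 of 27, 0.499), lysosome (21 of 25, 0.234), glycolysis (10 of 17, 0.237), disallowed genes (7 of 13, 0.237), cholesterol synthesis (12 of 25, 0.499), ATF4 targets (7 of 25, 0.58) and immediate early genes (5 of 18, 0.346). Falls were called for insulin processing and granules (13 of 18, 0.0802), FoxO targets (11 of 22, 0.346), autophagy (7 of 22, 0.234), ER chaperones (13 of 22, 0.237) and calcium handling (9 of 19, 0.242). Called the other way were 4 FoxO targets, 4 glycolysis genes, 3 autophagy genes, 1 disallowed gene, and 2 genes each of cholesterol synthesis, calcium handling and insulin processing and granules. The bracketed values are adjusted p with an estimated correlation. With p adjusted over the list alone, 13 cholesterol synthesis, 22 lysosomal, 13 glycolysis, 19 oxidative phosphorylation and 4 immediate early genes were higher, and 9 autophagy and 15 ER genes were lower. The call for immediate early genes was lost without Loperamide replicate 1 (0.11), without Loperamide replicate 2 (0.0641) and without FoxOi_Loperamide replicate 3 (0.0528). That for cholesterol synthesis was lost without Loperamide replicate 2 (0.0751). That for ATF4 targets was lost without Loperamide replicate 3 (0.126), without FoxOi_Loperamide replicate 1 (0.0556) and without FoxOi_Loperamide replicate 2 (0.0816).

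The largest rises by the naming rule were those of Stmn4 (5.28 ± 0.32), Areg (8 counts with loperamide, 410 with both compounds), Lgals3 (4.53 ± 0.41), Gpnmb (2 and 138 counts) and Mmp13. Mmp13 had 0 counts with loperamide and 14 with both compounds. Its mean was 3.57-fold above the floor, which leaves out the error of the 14 counts. Its call was lost without Loperamide replicate 1 (adjusted p = 0.0616), 2 (0.0733) or 3 (0.0748), without FoxOi_Loperamide replicate 2 (0.0734) or 3 (0.0712), and on unfiltered FPKM (0.639). The largest falls were those of Sphk1 (-5.14 ± 0.38), Muc4 (-5.03 ± 0.71), Grrp1 (-4.41 ± 0.55), Lyve1 (-4.08 ± 0.26) and Baiap3 (-4.07 ± 0.26). In all, 6541 genes were called, 3099 higher and 3442 lower, and 1581 changed at least 2-fold.

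**Figure D4:**
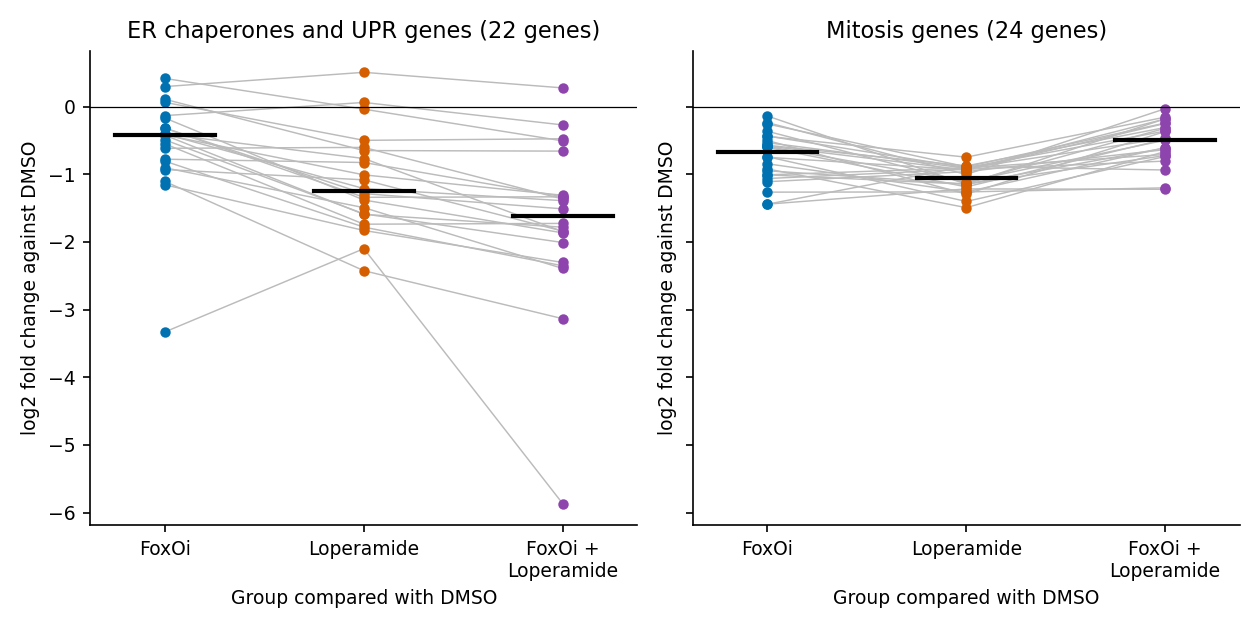
Log2 fold change against DMSO of each ER chaperone or unfolded protein response gene (22 genes, left) and each mitosis gene (24 genes, right) in the 3 treated groups; grey lines join a gene, and black bars are medians. The ER medians are -0.42, -1.25 and -1.62, and the mitosis medians are -0.67, -1.05 and -0.49.

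The overlap of calls shows how far each compound's effect was kept in the presence of the other. FoxOi vs DMSO and FoxOi_Loperamide vs Loperamide, which share no libraries, had 4223 genes called in both, 3998 of them in the same direction (1791 higher and 2207 lower, against 641 and 697 expected from the separate counts). Loperamide vs DMSO and FoxOi_Loperamide vs FoxOi had 2509 genes called in both, 2314 in the same direction (1065 higher and 1249 lower, against 311 and 401). FoxOi vs DMSO and FoxOi_Loperamide vs FoxOi had 2744 genes called in both, 1832 of them in opposite directions (1084 higher and 748 lower with FoxOi, against 525 and 390). That pair shares the FoxOi libraries, which pushes the fold changes apart: the covariance over genes was -0.186, against -0.0231 in 20 simulations without any effect, and the correlation -0.358 against -0.484. FoxOi vs DMSO and Loperamide vs DMSO, which share the DMSO libraries, had 2861 genes called in both, 1824 in the same direction (873 higher and 951 lower, against 561 and 538; covariance 0.0698, simulated 0.0254, and correlation 0.151, simulated 0.5). The simulations had a median of 0 genes counted for each of the 4 pairs. With no effect simulated, hardly any gene can be called in both comparisons, so this is not an expectation for overlap among changed genes. With the replicate number as a block, 2314 became 4208, 1832 became 3216 and 1824 became 3191.

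The interaction asks whether loperamide acted differently in the presence of the inhibitor. Mitosis genes had the clearest one: all 24 had a called positive interaction (median 1.29, adjusted p = 0.0253 with an estimated correlation). Gcg (1.68 ± 0.28, adjusted p = 0.00219), Mafa (1.07 ± 0.20, 0.00331) and Pdx1 (0.64 ± 0.12, 0.00251) had positive interactions. The values were 0.23 ± 0.19 for Ins1 (0.52), 0.17 ± 0.18 for Ins2 (0.648), 0.20 ± 0.16 for Nkx6-1 (0.511), 0.30 ± 0.15 for Foxo1 (0.245), 0.16 ± 0.13 for Pcsk1 (0.506) and 0.76 ± 0.47 for Slc2a2 (0.366). Foxo1 was called in 1 alternative, the replicate block (0.0397). Ucn3 was at -0.92 ± 0.31 (0.0829) and was called with no filter (0.0191), with the replicate block (0.00627), without FoxOi replicate 3 (0.0395) and without FoxOi_Loperamide replicate 1 (0.0437).

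Besides mitosis, autophagy (5 of 22 negative) and hypoxia (6 of 11 negative) held with an estimated correlation, each at an adjusted p of 0.0413. Negative interactions were also called for ATF4 targets (16 of 25, adjusted p = 0.162 with an estimated correlation), FoxO targets (7 of 22, 0.205), NRF2 targets (4 of 13, 0.192), immediate early genes (5 of 18 with 1 positive, 0.378) and calcium handling (4 of 19, 0.385). Positive interactions were called for beta cell factors (5 of 16, 0.192), alpha cell markers (4 of 9, 0.192), oxidative phosphorylation (4 of 27, 0.385), DNA replication (1 of 23, 0.641) and ribosomal proteins (1 of 22, 0.585). With genes adjusted over the list alone, 22 ATF4 targets, 8 autophagy genes, 8 FoxO targets, 7 NRF2 targets, 7 immediate early and 5 calcium handling genes had negative interactions, and 6 beta cell factors, 6 DNA replication and 8 oxidative phosphorylation genes positive ones. The call for calcium handling was lost with DESeq2 size factors (0.0504), without DMSO replicate 1 (0.148), without DMSO replicate 2 (0.071), without FoxOi replicate 2 (0.0561), without FoxOi replicate 3 (0.0835), without Loperamide replicate 3 (0.149), without FoxOi_Loperamide replicate 1 (0.0717) and without FoxOi_Loperamide replicate 2 (0.0654). That for immediate early genes was lost without DMSO replicate 1 (0.0558) and without Loperamide replicate 3 (0.173). That for DNA replication was lost without DMSO replicate 2 (0.0983), without Loperamide replicate 1 (0.132), without Loperamide replicate 3 (0.0888) and without FoxOi_Loperamide replicate 2 (0.0642). In all, 1594 genes were called, 616 with positive and 978 with negative interactions, and 610 differed at least 2-fold. With the replicate number as a block the count was 4334. The split by direction depended on single libraries, with 957 positive and 937 negative without DMSO replicate 3, and 485 positive and 597 negative without DMSO replicate 2. Progenitor and dedifferentiation genes, LXR targets of cholesterol efflux, and Notch pathway, mesenchymal and endothelial marker genes were not called as lists in any of the 6 comparisons with the main settings. Several members were too low to be tested, among them Neurog3, Sox9, Aldh1a3 and Fev of the progenitor and dedifferentiation list. Vim, Fn1 and Acta2 (mesenchymal) and Kdr and Cdh5 (endothelial) were also untested, so the list results do not cover these markers.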

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

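The tests for mitosis genes, mitochondrial transcripts and ERK targets were chosen only after the results had been seen, and the expectations for the splits were written after them too. The test of CREB targets was chosen before its result was seen.

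The interaction of FoxOi and Loperamide is taken up here because it tests a difference between 2 effects of the same compound, and 1594 genes and 13 lists passed. Among the named genes the log2 interaction was 1.68 for Gcg, 0.64 for Pdx1, 1.07 for Mafa, 2.31 for Dll1, 2.35 for Lrrn3, 2.79 for Adam32, 2.02 for St14 and 2.00 for Upk3a. It was -4.67 for Mylk2, -4.45 for Lyzl4, -5.69 for Cryab, -9.11 for Pla2g5 and -8.14 for Pla2g2e. The Cryab call was lost without Loperamide replicate 3 (adjusted p = 0.067) and the St14 call on unfiltered FPKM (0.0766). The Pla2g2e call was lost without Loperamide replicate 3 (adjusted p = 1) and without 8 other libraries: DMSO replicate 1 (0.0552) or 2 (0.0694), FoxOi replicate 1 (0.0506), 2 (0.06) or 3 (0.0571), and FoxOi_Loperamide replicate 1 (0.0549), 2 (0.0635) or 3 (0.0549). Pla2g2e and Pla2g5 have 0 counts in a group, so their fitted values depend on the prior count. Of 100 groupings of the 12 libraries, the real one included, 1 gave as many called genes as the real one, with 122 in the highest other. These groupings cannot decide whether chance is excluded, since the effects of the compounds enter the spread of every other grouping and the median of those was 0 genes. For each of the 5 pairwise comparisons the 10 splits of 6 libraries are too few for a share under 0.05. The real splits gave 6881, 5370, 7642, 4465 and 6541 genes, and the highest other split gave 0 in each, also among those that part all same-number pairs.

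Of 24 mitosis genes 21 were called lower with FoxOi, 24 with loperamide and 18 with both compounds against DMSO (adjusted p of the list with an estimated correlation 0.139, 0.0499 and 0.5), and 22 fell less with both than with loperamide alone. Within each replicate number their median interaction exceeded that of all tested genes by at least 1.27, computed from totals without scaling factors. This argues against the scaling of the libraries, which moves all genes of a library alike. With FoxOi alone the genes lay above their level with loperamide alone, by a median of at least 0.22 within each replicate number. A floor at the latter level would let loperamide lower them by that much in the presence of FoxOi, but the median of FoxOi_Loperamide minus FoxOi was at least 0.077 within each number, which argues against such a floor as the whole cause. Within the 3 replicate numbers the lowest median interaction was 1.25, so the pattern was present in each number. The genes were taken up because of their interaction in these same libraries. Their interaction within each number is therefore no independent test of whether a single set of libraries caused it. In FoxOi_Loperamide vs FoxOi 5 of the 24 were higher and 0 lower, so loperamide lowered none of them by a call once the inhibitor was present. An effect of loperamide on division that depends on the inhibitor may explain the pattern, which was found and tested on the same data. Cell number and cell cycle phase were not measured here.

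Mitochondrial transcripts changed unequally with loperamide: mt-Rnr2 rose by 2.65 ± 0.17 and mt-Nd2 by 1.31 ± 0.15, while mt-Cytb was at -0.17 ± 0.20 (adjusted p = 0.56). Of the 50-base stretches of mt-Rnr2, 1.04% occur in annotated transcripts of other genes, against shared reads as its cause; for mt-Nd2 the share is 8.19%, which lies between the bounds of the test and leaves it open, and the bounds of this test and the next were applied per gene only after the values were seen. The 5 tested nuclear RNAs without poly(A) tails had a median of 0.0716, or 0.68 with 2 SD over them added. Both lie below mt-Rnr2 and mt-Nd2 at their estimates minus 2 SE (2.32 and 1.02). For mt-Rnr2 this argues against greater capture of RNA without such tails as the whole cause of its rise. At their own estimates plus 2 SE, 5 of these RNAs lie below that bound for mt-Rnr2 and 3 for mt-Nd2. The highest of these values, 1.18, exceeds the bound for mt-Nd2, so the question stays open for mt-Nd2. No biological explanation is put forward for this pattern.

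Etv4, Etv5, Dusp6, Crem, Nr4a2 and Sik1, targets of ERK or CREB signalling, fell with loperamide. The highest of the 18 differences, 6 genes within 3 replicate numbers, was -1.23. The genes were taken up because they fell in these same libraries. Their fall within each number is therefore no independent test of whether a single set of libraries caused it. Further CREB targets, whose values had not been seen when their list was written, had a median of -0.0225, with 2 of 8 lower and 0 higher. The list was not called (camera p = 0.783, p = 0.804 with an estimated correlation), and lower CREB activity stays undecided. A list of 8 further ERK targets had a median of -0.46 (camera p = 0.00352, p = 0.048 with an estimated correlation), with 4 lower and 0 higher, which is consistent with lower ERK activity. That list is not independent evidence in full. The values of Plaur, Spred1 and Spry1 had been seen before it was written. The other 5 genes gave a median of -0.58 with camera p = 0.00226, or p = 0.0628 with an estimated correlation. Immediate early genes, a list fixed before the data were examined, were not called in Loperamide vs DMSO with the main settings.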

How the results depend on the processing

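All alternatives were chosen before the data were examined. Of the alternatives, the replicate block and the estimated correlation moved total counts by over 1.5 times. No library left out did so for a total, but by direction the interaction had 957 positive calls without DMSO replicate 3 (616 with all libraries) and 597 negative calls without DMSO replicate 2 (978), and FoxOi_Loperamide vs FoxOi had 1270 higher calls without FoxOi replicate 2 (1926). With the replicate block the called genes were 8179 for Loperamide vs DMSO, 7504 for FoxOi_Loperamide vs FoxOi and 4334 for the interaction. With that block 3216 genes were called in opposite directions in FoxOi vs DMSO and FoxOi_Loperamide vs FoxOi, 4208 were shared by Loperamide vs DMSO and FoxOi_Loperamide vs FoxOi, and 3191 by FoxOi vs DMSO and Loperamide vs DMSO. Of 18 same-number pairs of libraries, 17 correlated above 0.1, against 1 of 36 other pairs. A block takes such shared variation out of the spread, but whether this accounts for the higher counts was not tested. With the estimated correlation the called lists were 2 for FoxOi vs DMSO, 5 for Loperamide vs DMSO, 5 for FoxOi_Loperamide vs DMSO, 5 for FoxOi_Loperamide vs FoxOi, 3 for FoxOi_Loperamide vs Loperamide and 3 for the interaction, and the cause was not tested. Among the fixed lists, the replicate block added 4 calls. In Loperamide vs DMSO it added mitochondrially encoded genes (camera adjusted p = 0.00329, from 0.0514). In FoxOi_Loperamide vs DMSO it added mitochondrially encoded genes (0.00215, from 0.068), fatty acid synthesis (0.0213, from 0.068) and neuronal markers (0.0332, from 0.114). Among the same fixed lists, 10 calls were gained without the filter, and 21 with a library left out, for 12 pairs of list and comparison. Genes named here changed sign only where they were not called. With a library left out, Foxo6 in Loperamide vs DMSO ranged from -0.0386 (without DMSO replicate 3) to 0.225 (without DMSO replicate 1). Ins2 in Loperamide vs DMSO ranged from -0.259 (without DMSO replicate 3) to 0.0336 (without DMSO replicate 1), and Ucn3 in Loperamide vs DMSO from -0.248 (without DMSO replicate 3) to 0.0279 (without DMSO replicate 2). Ins2 in FoxOi_Loperamide vs FoxOi ranged from -0.00767 (without FoxOi_Loperamide replicate 1) to 0.165 (without FoxOi replicate 1), and Pcsk1 in FoxOi_Loperamide vs Loperamide from -0.041 (without Loperamide replicate 1) to 0.127 (without Loperamide replicate 2). Krt7 in FoxOi_Loperamide vs FoxOi ranged from -0.165 (without FoxOi_Loperamide replicate 1) to 0.155 (without FoxOi replicate 1). Krt7 was 0.00958 with DESeq2 size factors, 0.0295 with no filter, 0.0114 with DESeq2, 0.00785 with only the 2 groups compared, and on FPKM 0.00285 with pseudocount 1, 0.0027 with 0.1 and 0.00285 without the filter. Over the counted genes of the naming rule, printed here or not, calls were lost in 193 of the values with a library left out. On unfiltered FPKM they were lost in 52. No simulation varied depth, so what depth limits was not separated from the spread between libraries. At the depth of these libraries 24 of 67 simulated 1.5-fold changes were recovered for FoxOi vs DMSO. That simulation changed 200 genes, while 6881 were called in the data for this comparison. Fewer changes make the adjusted p threshold stricter, so this share does not give the recovery in the data.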

Other observations

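The 5 gene groups of this part and their tests were chosen after the data were seen. All 20 tested genes of transport from the ER to the Golgi fell with loperamide, with both compounds against DMSO and with both against FoxOi, Kdelr3 by 2.85 ± 0.18 and Sec24d by 1.45 ± 0.12 with loperamide (adjusted p = 0.000241 with an estimated correlation). In FoxOi vs DMSO 15 of the 20 fell (0.0544). Genes of the imprinted Dlk1-Dio3 locus fell with FoxOi in 4 of 5 cases (adjusted p = 0.0121 with an estimated correlation), while Rtl1 rose by 2.02 ± 0.55. Meg3 fell by 2.63 ± 0.17 and Rian by 2.57 ± 0.11, and with both compounds against DMSO they fell by 3.62 ± 0.18 and 3.79 ± 0.12 (log2, SE). With both compounds against DMSO all 5 fell, Rtl1 by 3.72 ± 1.24. With loperamide alone Mirg was the gene of the 5 called, at -0.71 ± 0.24 (adjusted p of the list 0.742 with an estimated correlation), while Meg3 was at 0.11 ± 0.15 (adjusted p = 0.629) and Rian at -0.17 ± 0.10 (0.22).

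Feedback genes of ERK signalling fell in 5 of 7 cases and rose in 1 with loperamide (adjusted p = 0.000511 with an estimated correlation), and fell in 6 of 7 and rose in 1 with both compounds against FoxOi (0.000484). In FoxOi vs DMSO 4 rose and 2 fell (0.469). Etv5 went from 41.8 ± 0.32 to 4.65 ± 0.32 CPM with loperamide (SD, n = 3). Matrix metalloproteinase genes rose in 5 of 7 cases with FoxOi (0.0673). The list of 5 tested nuclear RNAs without poly(A) tails was not called in Loperamide vs DMSO (median 0.07, adjusted p = 0.85). In FoxOi_Loperamide vs FoxOi the 8 further CREB targets had a median of -0.51 (camera p = 0.00233, p = 0.0249 with an estimated correlation) and the 8 further ERK targets a median of -0.99 (1.52e-11 and 0.000667).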
